A study of Arabidopsis thaliana with 4 samples.

How the data were processed

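Arabidopsis seedlings of the Landsberg erecta (Ler) accession and of a transgenic line, GR-REV, were grown in liquid culture and treated in the flask for 1 h. GR-REV expresses the HD-ZIP III transcription factor REVOLUTA, mutated so that its transcript escapes microRNA control, as a fusion to the hormone-binding domain of the glucocorticoid receptor, from the viral 35S promoter. Dexamethasone, a synthetic glucocorticoid, lets such a fusion enter the nucleus. One flask of each genotype received 50 µg/ml dexamethasone in 0.1% ethanol and one received the ethanol alone (mock). RNA from 100 mg of tissue per flask was hybridized to 1 Affymetrix ATH1 array, so there were 4 arrays and 1 array per group.

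The titles and treatment protocols of the 2 GR-REV arrays give one treatment to each, and the source names give them the other way round. Groups follow the titles and protocols here. With the source names, the sign of every difference between the 2 GR-REV arrays turns, and the array called GR-REV dexamethasone is the mock array. No condition was inferred from the values. The transgene itself was not analysed here, because no probe set is listed for REV in the annotation table used.

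The values are intensities on a linear scale, deposited as 1 signal per probe set, and the authors used MAS5, per the submitters' processing notes. MAS5 summarises perfect-match and mismatch probes, and its version was not given in the sources used here. The 2% trimmed mean of the signals was between 500.05 and 500.06 on the 4 arrays, so each array had been scaled to a common mean, and no further scaling was applied. The settings files deposited with the arrays hold other information, not RNA measurements, per the file headers: chip type, fluidics module and times. All 4 arrays were hybridized and scanned on 1 day at 1 fluidics station, each in a module of its own, so module and group cannot be told apart.

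Of 22810 probe sets, 64 control probe sets were left out. A floor at the 40th percentile of all signals, 91.4, was set before taking log2, because detection calls were not used here and low signals are mostly background. A value at the floor is a bound, and a fold against it is given as "at least". Above the floor lay 62.9% of probe sets on the wild type mock array and 59.0%, 59.2% and 58.9% on the GR-REV mock, wild type dexamethasone and GR-REV dexamethasone arrays. The number of arrays limits the precision. Gene names came from the platform's annotation table, updated through the RefSeq gene table of assembly TAIR10.1, which was used for names and for the order of neighbouring genes. Of the 22746 probe sets analysed, 13513 had 1 gene, 503 had several and 8730 had none listed; the last are unnamed here, not without a gene. Of the first, 13436 matched the RefSeq table.

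With 1 array per group the dexamethasone comparisons have no replicate error and no test. A difference of at least 2-fold was the fixed rule. Beside single genes stands the central 99% of the wild type pair's differences among the 1000 probe sets nearest in mean level, which holds any effect of dexamethasone on wild type too. Genotype was tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend) on 2 GR-REV against 2 wild type arrays, with 2 residual degrees of freedom and a Benjamini-Hochberg adjusted p under 0.05. That test does not use the disputed treatments. Treatment was tested in the same way with genotype as a term and 1 residual degree of freedom. Probe sets above the floor on at least 2 arrays were tested, 14034 in all. The labels name 1 flask per group, so no p-value rests on replicate flasks. In the genotype test the spread is the difference between the mock and dexamethasone flasks of each genotype, with any response to treatment. In the treatment test it is the difference between the responses of the 2 genotypes. A response to the fusion alone therefore counts as error there.

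On simulated arrays, the 2-fold rule for GR-REV dexamethasone over mock found 90% of probe sets changed by 1.5 on the log2 scale, among 15174, and all of those changed by 2.5. The rule that GR-REV dexamethasone lies 2-fold apart from each other array found 78% and all. The limma genotype test found 97% of 100 probe sets changed by 1.5, among 14147 simulated, and the treatment test 95% of 100 among 14206. With no change simulated and the noise of the wild type pair, 110 probe sets were 2-fold higher and 140 lower in the GR-REV pair. The simulated noise was normal, with the central spread of the wild type pair, and understates the tails: that pair itself had 507 probe sets past 2-fold. The simulated counts are therefore no yardstick for the observed ones. The simulated changes were placed only in probe sets well above the floor, so the shares found do not hold for those near it. The narrow noise may also make these shares too high. With no change simulated, limma called 1 probe set for genotype and 2 for treatment among 14174. In the same simulation as for the pairs 24 lay 2-fold above the other 3 arrays and 0 below.

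The rules, gene lists and most alternatives were fixed before the data were examined. Genes are named by rule: members of lists of LITTLE ZIPPER genes, HD-ZIP III genes and reported REV targets, the 12 highest and 8 lowest by the smallest difference of GR-REV dexamethasone to the other 3 arrays among those above the floor on all 4 arrays, up to 4 above the floor only in GR-REV dexamethasone, the 6 highest and lowest differences in each dexamethasone pair with both arrays above the floor, the 8 highest and lowest called differences between genotypes among those above the floor on all 4 arrays, and up to 4 members of every other list that differed at least 2-fold in the GR-REV pair. Each of these needed exactly 1 gene. Genes outside the rule were chosen after their values were seen, apart from further list members, which are named where their list is described. The 25 lists held 559 members, of which 68 could be matched to a probe set in the annotation, and 0 lists reached 80% coverage, so checks of a list as a whole are void and medians describe the measured members. Among the 68, the symbols FDH and CCR2 belong to other genes than those the lists meant, and their values are not reported. A list's median was set against 10000 random lists of the same size matched on level in 20 bins.

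Alternatives were quantile normalization, division by each array's median, a floor at the 25th or 60th percentile, the floor value added in place of a floor, a 3-fold threshold, treatment as a term in the genotype test, leaving out each array, and the treatments as the source names give them. Added after the files were seen were limma on probe sets above the floor on all 4 arrays, the count of GR-REV dexamethasone apart without the wild type mock array, and the settings of the chromosome 3 segment and of the UGT genes.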

Results

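Transcript levels were measured in 4 flasks of seedlings, wild type or GR-REV, 1 h after dexamethasone or mock treatment, with 1 array per group. For the 2 GR-REV arrays the titles and the source names give opposite treatments; groups here follow the titles, and if the source names are right, every difference between these 2 arrays has the other sign. The study's stated aim was to find immediate targets of REVOLUTA, which appear as genes that differ only where both the fusion and dexamethasone are present. Median signals were 181 in wild type mock, 161 in GR-REV mock, 156 in wild type dexamethasone and 163 in GR-REV dexamethasone. Across 12252 probe sets above the floor on all arrays, Pearson's r was 0.964 for the wild type pair and 0.963 for the GR-REV pair, and 0.917 to 0.937 between genotypes; probe sets are not independent replicates. At most 1 probe set had an identical value on any 2 arrays.

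The array titled GR-REV dexamethasone stood out for HAT2, an HD-ZIP II transcription factor gene that responds to auxin. Its signal was 1074 there, against 450.0 in wild type mock, 463 in wild type dexamethasone and 405 in GR-REV mock. This was 2.65-fold higher than in GR-REV mock, or 1.41 on the log2 scale, above the wild type pair's central 99% of -1.31 to 1.18. In wild type, the HAT2 difference with dexamethasone was 0.04. HAT2 was on the list of reported REV targets made beforehand, of whose 11 members only 2 could be matched to a probe set.

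Among genes above the floor on all 4 arrays, the highest by distance from the others was AT3G50560, with a signal of 1145 against 161 to 174 on the others, at least 6.57-fold higher than each. AT1G32090 was 3.91-fold and AT5G50335 3.15-fold above the nearest other array, and AT3G22240 had a signal of 4665 against 1413 on the nearest. AT3G12710 followed with 2.91-fold, AT1G49200, which encodes a RING finger protein, with a signal of 1291 against 460.3, AT4G09890 with 2.78-fold and AT5G47060 with 2.61-fold. The GDSL-type lipase gene AT4G18970 was 2.68-fold higher than in the nearest array and 5.25-fold higher than in GR-REV mock. XTH32, a xyloglucan-modifying enzyme of the cell wall, was 2.47-fold and AT2G36630 2.41-fold above the nearest array. In these 12 genes including HAT2, the difference within the GR-REV pair lay outside the wild type pair's central 99%. This follows in large part from their choice, since the ranking counted the distance to GR-REV mock. AT1G70985, AT3G46490, AT4G21740 and AT1G33790 were above the floor only in GR-REV dexamethasone, at least 8.07, 5.73, 2.78 and 2.45-fold above it.

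In the other direction, AT1G52000, a jacalin-type lectin gene, had a signal of 125 in GR-REV dexamethasone and 503 in GR-REV mock, a 4.02-fold difference. It was also 3.26-fold lower with dexamethasone in wild type, 840.2 against 2740.3. AT4G22212, a defensin-like gene, was 3.78-fold and the TIR-domain gene AT1G72920 was 2.96-fold lower than in the nearest array. PDF1.2b, a plant defensin gene, was at 1854 in GR-REV dexamethasone and between 6287 and 6447 elsewhere; its probe set is of a kind that can cross-hybridize with related genes. AT3G51450 was 2.53-fold, AT1G49470 2.27-fold and CHX20, a cation/proton exchanger of guard cells, 2.31-fold lower. AT5G54130 was 2.41-fold lower than in the nearest array on one of its probe sets; on the other the GR-REV difference was -0.77, against -1.84. For AT3G51450, CHX20 and AT1G49470 the GR-REV difference lay within the wild type pair's central 99%, for AT3G51450 only just (-1.338 against -1.342). AT4G22212, AT1G72920, AT3G51450 and AT1G49470 were also 1.92, 1.70, 1.70 and 1.85-fold lower with dexamethasone in wild type. In GR-REV mock they differed from wild type mock by -1.39, -1.12, -1.10 and -1.21 on the log2 scale. Their low place in GR-REV dexamethasone therefore holds both differences. In wild type, PDF1.2b, AT5G54130 (first probe set) and CHX20 differed by -0.04, -0.29 and -0.20. With a floor at the 60th percentile, only PDF1.2b and AT3G51450 of the genes in this paragraph stayed 2-fold below each other array. With the floor value added, AT5G54130, CHX20 and AT1G49470 fell short of 2-fold.

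**Figure D1:**
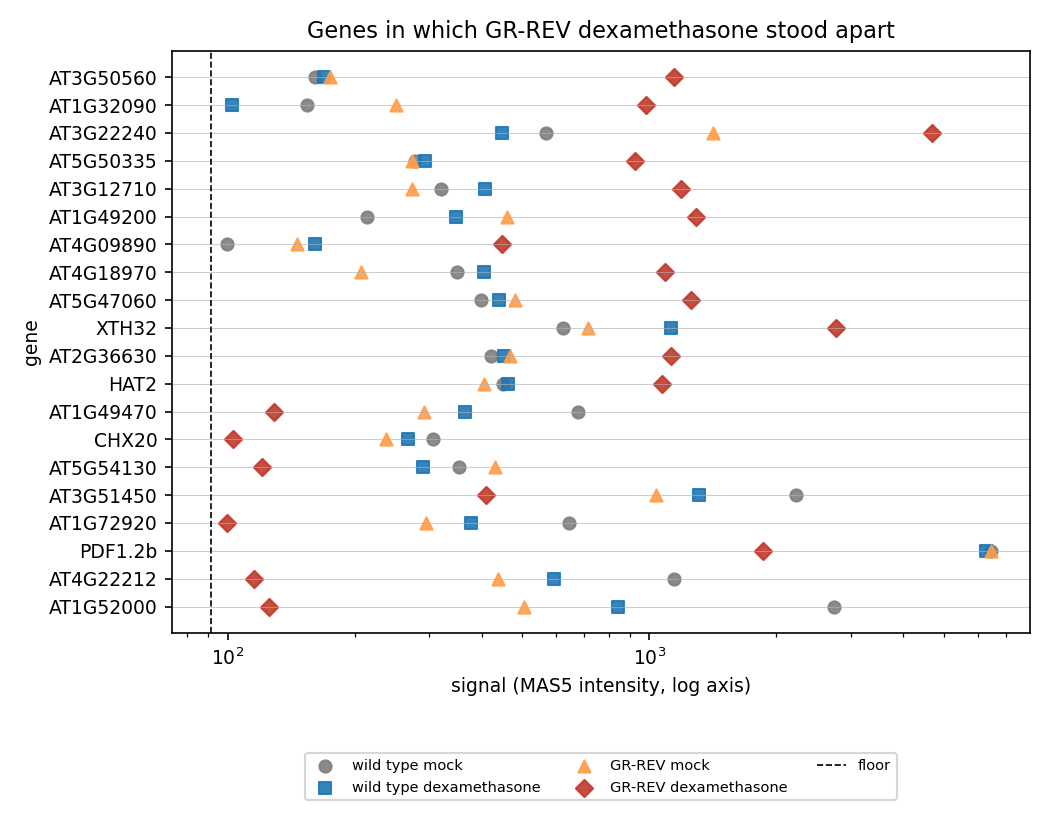
Signal on each of the 4 arrays (horizontal log axis, MAS5 intensity) for the 12 genes with the highest and the 8 with the lowest signal in GR-REV dexamethasone relative to every other array, among genes above the floor on all 4; symbols mark the arrays and the dashed line the floor of 91.4. AT3G50560 lay at 1145 in GR-REV dexamethasone and at 161 to 174 on the other arrays.

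Of all probe sets, 89 were at least 2-fold above and 73 at least 2-fold below each of the other 3 arrays in GR-REV dexamethasone. The same count was 109 and 16 for wild type mock, 61 and 51 for GR-REV mock, and 36 and 51 for wild type dexamethasone. At 3-fold the totals were 26 for GR-REV dexamethasone, 13 for wild type mock, 13 for GR-REV mock and 7 for wild type dexamethasone. The probe set farthest above the other arrays, seen after its values were known, has no gene listed and is not named here. There is no replicate check on any of these differences, and with the source names the array that stands apart is the mock array. With a floor at the 60th percentile the counts were 45 above and 31 below, and with the floor value added 50 and 33, of which 50 and 30 were among the 89 and 73.

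Within the GR-REV pair, the highest named genes besides AT3G50560, AT4G18970 and AT3G12710 were the GDSL-type lipase gene AT4G28780 at 4.66-fold, AT4G22490 at 4.12-fold and AT1G12080 at 2.04 on the log2 scale. AT4G22490 and AT1G12080 were also higher with dexamethasone in wild type, 2.68-fold and 2.19-fold. The lowest were AT5G39520 at 5.44-fold, OSM34, an osmotin-like gene, at 5.04-fold, AT4G10270 at 4.09-fold, AT1G52000, AT2G36690 at 3.95-fold and the beta-1,3-glucanase gene AT4G16260 at 3.83-fold lower. For all of these but AT1G52000 it was the GR-REV mock array that held the highest signal, 1522 for OSM34 against 180.1 in wild type mock, 722 in wild type dexamethasone and 302 in GR-REV dexamethasone. OSM34 was 4.01-fold higher with dexamethasone in wild type.

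In all, 278 probe sets were at least 2-fold higher and 275 at least 2-fold lower in GR-REV dexamethasone than in GR-REV mock, 553 in all, against 507 in the wild type pair. Of the higher, 135 had 1 gene, and 185 lay outside the wild type pair's central 99%. Of the lower, 113 had 1 gene and 103 lay outside it. That range was lopsided (-1.31 to 1.18 at the level of HAT2) and depends on how the wild type arrays are scaled. The yardstick was therefore not equal for higher and lower probe sets. In 89 of the 278, GR-REV dexamethasone was also 2-fold apart from both wild type arrays, in 51 GR-REV mock was, in 1 both were and in 139 neither. In the 275, these numbers were 73, 61, 1 and 142. The floor decides much of the count: at the 25th percentile it was 508 higher and 510 lower, and at the 60th 125 and 128.

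For most members of the hormone and stress lists the annotation used names no probe set, so they were not analysed here. Of the HD-ZIP III genes only PHV could be matched, with 0.29 in the GR-REV pair and -0.31 in wild type on the log2 scale, and of the LITTLE ZIPPER genes none could be. WRKY53, a senescence regulator on the list of reported targets, was 1.53-fold higher with dexamethasone in GR-REV and 2.32-fold lower in wild type. The auxin-conjugating enzyme gene GH3.3 was 2.44-fold lower in the GR-REV pair and 1.59-fold lower in wild type; the 5 auxin response members above the floor had a median of 0.00. PUB22, a ubiquitin ligase gene, was 2.38-fold lower and AT5G48570, a heat-induced FKBP-type gene, 2.42-fold higher in GR-REV dexamethasone, where UGT73B4 was 2.16-fold and STOMAGEN, which promotes stomata, 2.40-fold higher than in GR-REV mock. The abaxial genes YAB3 and YAB5 differed by 0.23 and 0.39. Medians in the GR-REV pair were 0.23 for the 3 abaxial genes, 0.00 for 7 touch genes, 0.41 for 3 detoxification genes, -0.05 for 7 photosynthesis genes, 0.00 for 3 stomatal genes, 0.32 for 3 cell division genes and -0.12 for 3 gibberellin receptor genes, between the 25.95th and the 96.0th percentile of random lists. Several of these depend on members at the floor: with a floor at the 25th percentile the medians were 0.35 for auxin response, 1.03 for detoxification and 1.04 for stomatal genes, and at the 60th 0.00 for detoxification and cell division.

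In wild type, dexamethasone alone went with higher signals for AT3G13610, which encodes F6'H1 of coumarin synthesis, at 6.61-fold, for the methyltransferase gene AT1G73600 at 4.69-fold, OSM34, AT1G62480 with 3794 against 1187, AT3G18250 at 3.15-fold and AT5G46230 at 2.93-fold. AT3G13610 was also 3.81-fold and AT1G73600 2.05-fold higher with dexamethasone in GR-REV. The lowest were AT3G44140 at 4.94-fold, AT3G53980 at 4.08-fold, AT4G22470 at 3.47-fold, AT1G80130 at 3.32-fold, AT1G52000 and AT2G43160 at 3.25-fold lower, the last on only one of its probe sets, as the other differed by -0.12. In all of these but AT4G22470, wild type mock held the highest signal, and GR-REV mock was also lower than it, without the hormone. AT3G44140 had 829 in wild type mock, 131 in GR-REV mock, 168 in wild type dexamethasone and 118 in GR-REV dexamethasone. Each of the higher genes above had its lowest signal in wild type mock. AT1G62480 and AT3G18250 were at 5461 and 1443 in GR-REV mock, without the hormone, against 1187 and 397 in wild type mock. All 3 gibberellin receptor genes were lower in wild type dexamethasone, GID1A by -0.69, GID1B by -1.01 and GID1C by -0.72. GID1B was also 2.32-fold lower in the GR-REV pair, within the wild type pair's central 99%. The GID1 median of -0.72 lay at the 1.67th percentile of random lists, and that of 7 touch genes, -0.47, at the 2.04th. At the other end, 3 stomatal genes had a median of 0.51 in wild type, at the 99.02th percentile, and 3 cell division genes 0.12, at the 91.9th.

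There were 126 probe sets at least 2-fold higher and 381 lower with dexamethasone in wild type. This split depends on the scaling: it was 212 and 249 after quantile normalization and 310 and 176 with division by the median, which moves the median of all probe sets from -0.06 to 0.16. The wild type mock array had the highest share of probe sets above the floor, 62.9%, and a 25S rRNA control signal of 293 against 768 to 929 on the others.

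**Figure D2:**
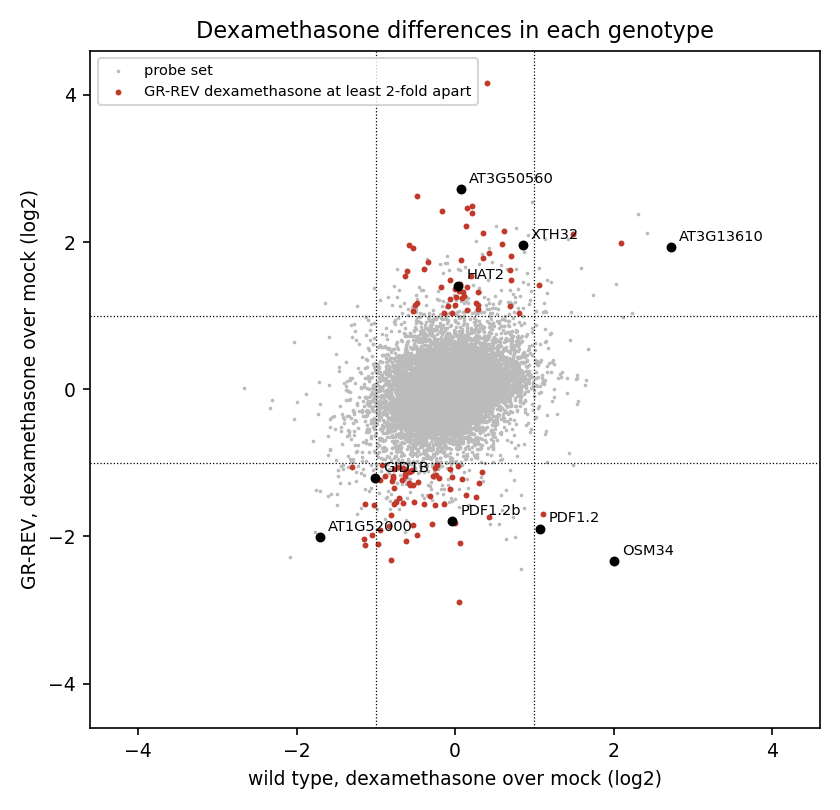
Log2 difference of dexamethasone over mock in wild type (horizontal) and in GR-REV (vertical) for 12252 probe sets above the floor on all arrays; red points are probe sets in which GR-REV dexamethasone lay at least 2-fold apart from each other array, black points are named genes and dotted lines mark 2-fold. HAT2 and AT3G50560 lie near 0 in wild type, at 0.04 and 0.07, and OSM34 lies at 2.00 in wild type and -2.33 in GR-REV.

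The jacalin-type lectin gene AT1G52000 was the only probe set with 1 gene that changed with dexamethasone over both genotypes in the limma treatment test: it fell by 1.86 ± 0.19 (SE) on the log2 scale (adjusted p = 0.0488, lower in both pairs). Also called were 1 probe set with several genes, which fell, and 4 with no gene listed, which rose, making 6 against 2 calls with no change simulated, where the noise was narrower than that of the arrays. The 26 probe sets at least 2-fold higher with dexamethasone in both pairs compare with 2.31 for independent lists, and the 52 lower with 6.90; the 2 pairs share no array. The differences in both pairs had r = 0.275 and rho = 0.262 across 12252 probe sets. These 6 calls of 14034 tested became 84 after quantile normalization and 418 with division by the median. With the treatments of the source names there were 0 limma calls (256 at an unadjusted p under 0.05, against 1615) and r was -0.275.

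Genotype made the larger difference. Among called genes above the floor on all 4 arrays, AT2G25450, a gene of the 2-oxoglutarate-dependent dioxygenase family, was higher in GR-REV by 4.22 ± 0.26 (SE, 2 against 2 arrays) on the log2 scale, with signals of 7882 and 4874 against 308 and 357 in wild type. Also higher were AT5G44580 by 3.16 ± 0.34, AT5G24570 by 3.13 ± 0.19, AT5G45510 by 2.99 ± 0.24, AT1G47400 by 2.78 ± 0.26, AT2G21860 by 2.62 ± 0.22, the co-chaperone gene AT4G02450 by 2.61 ± 0.27 and AT2G33220, a subunit of mitochondrial complex I, by 2.45 ± 0.17. Adjusted p in limma was between 0.00548 and 0.0223 for these 8 genes.

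Among called genes above the floor on all 4 arrays, lower in GR-REV were AT1G13470, 8.02-fold, the light-harvesting gene LHCB4.3, at -2.71 ± 0.21, and SAPX, the stromal ascorbate peroxidase, at -2.53 ± 0.18. They were followed by the chitinase family gene AT2G43590 at -2.45 ± 0.30, AT5G46730 at -2.39 ± 0.29, AT4G11000 at -2.24 ± 0.34, AT2G32160 at -2.11 ± 0.28 and AT1G68650 at -2.10 ± 0.32. Adjusted p in limma was between 0.00807 and 0.0464. Chosen after their values were seen, AOP3, a glucosinolate side-chain enzyme, had signals of 6068.5 and 4400.1 in wild type and 30.4 and 5.50 in GR-REV, at least 56.6-fold lower, and AT3G48640 was lower, at -4.33 on the log2 scale as a bound. AT2G25510 had 18578 and 19289.7 in GR-REV and 139.7 and 68.0 in wild type, and QQS (AT3G30720), a starch regulator, was at least 16.3-fold higher in GR-REV.

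The limma genotype test called 180 probe sets higher and 69 lower in GR-REV, of which 98 and 42 had 1 gene. Of these calls, 100 were at least 4-fold, 25 were at the floor on both wild type arrays and at least 4-fold above it in GR-REV, and 8 the reverse. Without the wild type mock array 97 and 17 were called, without wild type dexamethasone 61 and 20, without GR-REV mock 198 and 170, and without GR-REV dexamethasone 178 and 125. With treatment as a term 568 and 429 were called.

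One stretch of chromosome 3 stood out when genes were put in the order of their locus tags, which was done after the genotype calls were seen. From AT3G16330 to AT3G19590 lay 92 genes measured on all arrays. Their median difference, GR-REV over wild type, was 0.92 on the log2 scale in the mock arrays, from which the borders were set. It was 1.03, or 2.04-fold, in the dexamethasone arrays, which did not set the borders, although the genotype calls had used them. In the dexamethasone arrays 87 of the 92 lay above 0. The quartiles were 0.73 and 1.35, against -0.25 and 0.28 for the other 1237 genes of the chromosome. Members included UGT88A1, a glycosyltransferase, by 1.58 ± 0.21 (adjusted p = 0.0344, limma), HDA15, a histone deacetylase, by 1.74 ± 0.25 (0.0420), and the jacalin genes JAL33 and JAL34 by 1.01 ± 0.19 (0.0731) and 1.12 ± 0.19 (0.0589), which did not pass. The summed excess of the segment was 33.8, against 7.06 for the highest of 1000 random gene orders and 4.29 for the next chromosome. HAT3.1, a homeodomain gene, was higher by 1.27 ± 0.24 (adjusted p = 0.0734, limma), and AT3G18250 also lies in the stretch.

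**Figure D3:**
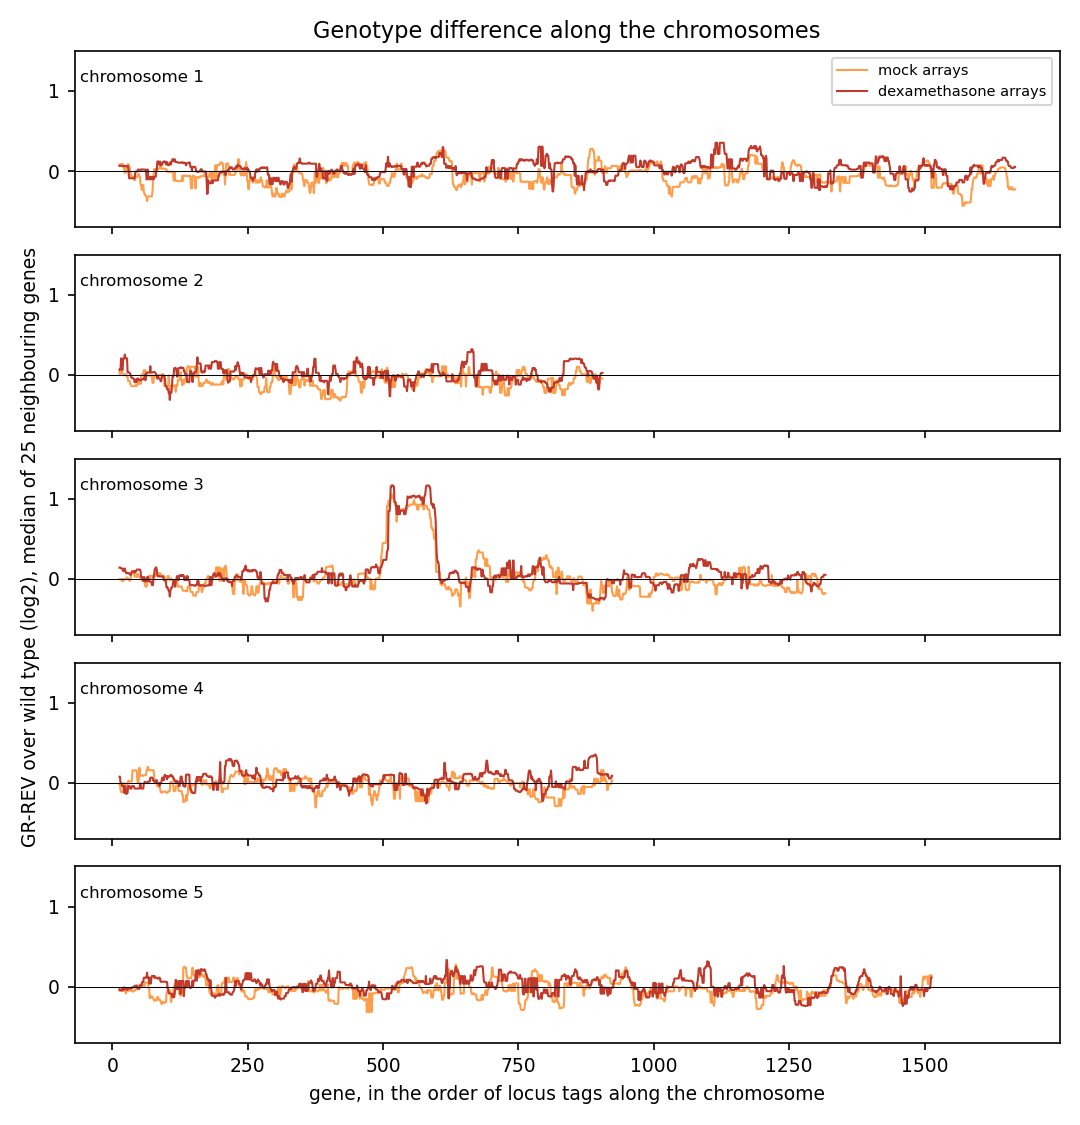
Genotype difference, GR-REV over wild type on the log2 scale, as the running median of 25 neighbouring genes in the order of locus tags (horizontal axis, gene number along each of the 5 chromosomes), drawn for the mock arrays and for the dexamethasone arrays. On chromosome 3 both lines reach a plateau near the medians of 0.92 and 1.03, and elsewhere they stay near 0.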

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

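Results are listed here because the dexamethasone difference had opposite signs in the genotypes, or because a control signal outside the comparisons differed between arrays. The 3-fold threshold and quantile normalization were chosen before the data were examined, and their use as tests of an explanation was chosen after the results were seen.

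OSM34, an osmotin-like gene, was lower with dexamethasone in GR-REV, -2.33 on the log2 scale, and higher in wild type, 2.00. PDF1.2, a defensin gene that responds to jasmonate, was lower in GR-REV, -1.89, and higher in wild type, 1.07. With the treatments of the source names, OSM34 and PDF1.2 each had the same sign in both genotypes. Opposite signs were fewer than like signs at this size. Of the probe sets at least 2-fold higher and lower in the GR-REV pair, 4 and 5 were 2-fold the opposite way in wild type. By comparison, 26 and 52 went the same way. The number for independent lists was computed only for the same way, so these counts do not set OSM34 and PDF1.2 apart. With 1 array per group the differences of OSM34 and PDF1.2 between genotypes were not tested. The 25S rRNA control was 3.17-fold higher in GR-REV dexamethasone than in wild type mock, and the bacterial and phage hybridization controls were 1.52-fold higher in wild type dexamethasone than in GR-REV mock. The actin control's signal at the end of its transcript over that at its start also differed. This ratio was 2.92 in GR-REV mock and 2.86 in wild type dexamethasone, against 2.17 in wild type mock and 1.95 in GR-REV dexamethasone.

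GR-REV dexamethasone lay at least 3-fold apart from the other arrays in 26 probe sets, among them AT3G50560. Variation between single flasks or arrays was weighed through the other arrays, of which the highest number was 13. That is fewer than 26 but not near 0, so such variation may account for part of the list and stays open. Scaling between arrays was weighed by quantile normalization, after which 90.7% of the 162 probe sets at least 2-fold apart were called again, so scaling does not account for the list. The biological explanation, a response to the activated fusion, was not tested apart from the flask, because each group had 1.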

How the results depend on the processing

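Many counts moved with the processing, and the cause was not tested. The count without the wild type mock array (108 above, 84 below), the filter on all 4 arrays (168 higher, 75 lower in GR-REV) and the settings for the segment and the UGT genes were chosen after the data were seen. No paired analysis was possible because the labels number no replicates that groups share; genotype and treatment entered only as terms. With 1 array per group no array could be left out of a dexamethasone comparison.

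Quantile normalization gave 212 higher and 249 lower with dexamethasone in wild type and 84 limma treatment calls. Median scaling gave 310 and 176 in wild type, 418 treatment calls, and 302 higher and 125 lower in GR-REV in the limma genotype test. With a floor at the 25th percentile there were 508 and 510 in the GR-REV pair, 253 and 1123 in wild type, 150 below the other 3 arrays in GR-REV dexamethasone, and 62 treatment calls. With a floor at the 60th percentile there were 125 and 128, 68 and 109, and 45 above and 31 below the other arrays. With the floor value added there were 151 and 151, 72 and 151, 50 above and 33 below, 282 and 136 genotype calls, and 2 treatment calls. At 3-fold these were 68 and 48 in the GR-REV pair, 19 and 34 in wild type, and 16 above and 10 below the other arrays.

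With the treatments of the source names there were 0 treatment calls and r between the 2 pairs was -0.275. For a single gene the sign of the GR-REV difference turns. A gene apart in GR-REV dexamethasone, such as HAT2, is then apart in GR-REV mock, without the hormone. Treatment as a term gave 568 higher and 429 lower in GR-REV. Leaving out each array gave 61 to 198 higher and 17 to 170 lower, and 71 to 174 of the 249 calls were called again. Each of these fits has 1 array in one genotype, so the other genotype supplies all the spread. With the floor value added the list medians were 0.25 for auxin response and 0.53 for stomatal genes. The segment's median was 0.78 to 1.09 in the mock arrays and 0.85 to 1.03 in the dexamethasone arrays over the settings.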

Other observations

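UDP-glycosyltransferase (UGT) genes, which attach sugars to hormones, phenolics and foreign compounds, were mostly lower with dexamethasone in both genotypes, with the treatments of the titles. With those of the source names they were mostly higher in GR-REV and lower in wild type. Of 29 UGT genes measured above the floor on an array, 21 were lower and 6 higher in the GR-REV pair, with a median of -0.40 on the log2 scale, and 23 were lower and 2 higher in wild type, with a median of -0.41. UGT85A2 had signals of 1266 and 1309.8 in the mock arrays and 533 and 554 in the dexamethasone arrays, and UGT84A3 had 563 and 670.1 against 298 and 325. UGT74B1, a glucosinolate synthesis enzyme, had 3509 and 3049 against 2623 and 1833, while UGT76B1 and UGT74D1 were higher in GR-REV dexamethasone, by 0.31 and 0.73. Of 10000 random lists matched on level, 0 had medians as low in both pairs; UGT was 1 of 18 families examined after the values were known. With median scaling the wild type median was -0.20, with 19 of 29 lower. Relative to all probe sets, the medians were -0.39 and -0.38 after quantile normalization, and with a floor at the 60th percentile they shrank to -0.07 and -0.02 before that subtraction.

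Of 38 touch and rapid stress genes on the list, only 7 could be matched to a probe set, so nothing follows for the list as a whole. CML38, a calmodulin-like gene, was called lower in GR-REV in the limma genotype test, at -1.59 (adjusted p = 0.0432). PUB22 at -0.72, PUB23 at -1.26, PUB24 at -0.59 and the zinc finger gene STZ at -0.90 did not pass, nor did WRKY53 at 0.47, and CML37 was above the floor on 1 array only. The median of the 7 was -0.72, at the 0.03th percentile of random lists. The 9 BGLU and 8 tetraspanin genes had medians of -0.49 each, at the 0.095th and 0.19th percentiles, but members went both ways. BGLU15 was lower in GR-REV by a tested difference of -1.91 (adjusted p = 0.0332, limma), while BGLU25 at 1.43, BGLU44 at 0.92, BGLU42 at 0.84, TET3 at 0.97 and TET7 at 0.57 were on the higher side without passing.

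All tests in the next paragraphs were chosen after the pattern was seen. A candidate explanation for the plateau on chromosome 3 is an extra copy of the segment from AT3G16330 to AT3G19590 in the GR-REV line. That predicts a shift of nearly every gene by a like amount. The median in the dexamethasone arrays, which did not set the borders of the segment, was 1.03, close to a doubling. The genotype calls that came before the search had used these arrays too. Sequence differences at single probes would leave most genes near 0, whereas the 25th percentile was 0.73. Activity of the fusion set off by dexamethasone would raise the segment over GR-REV mock, where its median difference was 0.042 (bootstrap interval -0.02 to 0.11). The bootstrap drew genes, so its interval holds no variation between flasks. The segment was also chosen as high in GR-REV mock, without the hormone, which lowers the difference over that array. This median therefore describes the segment and cannot decide on such activity. The extra copy remains a hypothesis, since no DNA was measured, and whether it lies with the transgene was not tested.

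Outside that segment, 119 genes were called between genotypes, 79 of them higher in GR-REV, including QQS and AT2G25510, and the others lower, including AOP3. A genetic background that differs from that of the wild type arrays may account for these, because AOP3 is known to differ in expression between accessions, although a title of the GR-REV arrays names the line as Ler. It predicts calls on all 5 chromosomes, and the lowest ratio of observed to expected calls was 0.736, on chromosome 3, with 17 genes called. Activity of the fusion without dexamethasone predicts a further rise with the hormone. In probe sets at least 4-fold above both wild type arrays the averaged median difference of GR-REV dexamethasone over mock was -0.035 (bootstrap interval -0.14 to 0.05). No such rise appeared in these probe sets as a whole. The bootstrap drew probe sets, so its interval holds no variation between flasks. A median also cannot tell whether a minority of the calls responds to the fusion. An even spread over chromosomes would also follow from a response to the fusion that the hormone does not raise, which stays open. Sequence differences at single probes were weighed only inside the segment, so a call outside it need not be a difference in transcript level.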
